A study of Homo sapiens with 2 samples.

How the data were processed

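Gene expression was compared between wild-type A549 cells (WT) and A549 cells overexpressing MYOCD. A549 is an established human lung adenocarcinoma line of alveolar epithelial origin. MYOCD encodes myocardin, a coactivator of the transcription factor SRF in smooth and cardiac muscle. Per the labels' protocols, cells were grown in DMEM with serum, total RNA was taken with Trizol and libraries were made with an Illumina TruSeq RNA kit. The labels give 1 library in each of the 2 groups, so no value has a replicate error and p-values were not used.

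The expression values are RPKM (reads normalised to gene length and to the size of the library), per the file headers, as the authors deposited them. The header of the WT column carries an abbreviation that the sources used here do not explain, and a key at the head of the table defines that column as WT. Bowtie 0.12.2 and the genome builds mm8 and GRCh38.p12 are named in the submitters' processing notes. The build mm8 is a mouse assembly, while the gene identifiers of the table are human, and whether it was used for these libraries is not given in the sources used here. The role of each, the counting tool, the gene annotation it used and whether it used strand are not given in the sources used here. RPKM holds no counts, so sequencing depth is unknown and no counting intervals were computed. Low values of gene models with 1 transcript and a length of at least 2000 nt were searched for the step that 1 read makes. The candidate steps gave a ratio of MYOCD to WT depth of 0.881. Within a tolerance of 0.1 of a whole number lay 30.9% of low values in WT and 33.0% in MYOCD, where chance gives 20%, so whole reads were not recovered, the ratio is uncertain and was not used, and no count test was run.

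The table has 57979 gene rows with 56255 symbols, of which 248 stood on several rows. For those, the row with the higher mean RPKM was used. Gene positions, types and model lengths came from GENCODE release 29 on GRCh38, which held 57375 of the identifiers. Length was the union of a gene's exons. For each gene the log2 change was computed as log2((MYOCD RPKM + 0.5)/(WT RPKM + 0.5)). The pseudocount of 0.5 RPKM understates the change of genes with low values, and a fold change on this scale is smaller than the ratio of the deposited values. Genes with an RPKM of at least 1 in at least 1 library were counted, and a gene at or beyond 2-fold (log2 of 1 or more in either direction) was called higher or lower. This is a rule of size and not a test.

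For each gene list, the median log2 change of the members past the filter was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins (random seed 1). Percentiles at or under 2.5 or at or above 97.5 were read as standing apart. Such a percentile describes these libraries and is no p-value, because genes of a list are not independent and each group is a single culture. Lists with fewer than 5 members past the filter have counts only. The primary lists were smooth muscle contractile genes, cardiac and sarcomere genes, SRF and actin cytoskeleton target genes, mesenchymal and EMT transcription factor genes, epithelial junction and identity genes, and TGF-beta pathway and response genes. The secondary lists were BMP and ID genes, proliferation genes, p53 target genes, NRF2 target genes, interferon-stimulated genes, inflammatory and NF-kB genes, unfolded protein and integrated stress response genes, heat shock genes, hypoxia and glycolysis genes, cholesterol synthesis genes, nuclear oxidative phosphorylation genes, YAP and TEAD target genes, Notch target genes, Wnt target genes, integrin and basement membrane genes, alveolar and airway lineage genes, and skeletal muscle transcription factor and miRNA host genes. The check lists were fibroblast, endothelial, blood cell, neural and germ cell, and liver and gut markers, ribosomal protein genes, mitochondrially encoded genes, replication-dependent histone genes and steady reference genes.

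The genes to be named were MYOCD, the 12 genes with the largest and the 12 with the smallest log2 change among genes with an RPKM of at least 5 in the higher library, up to 6 members of each list at or beyond 2-fold (with the most abundant members added up to 3), and the 5 genes with the highest mean RPKM. The design, lists, naming rule and alternative settings were fixed before the data were examined. That rule named very short gene models at both ends. The 12 largest and 12 smallest changes were therefore also taken among protein-coding genes with no GENCODE transcript under 200 nt and no small RNA gene inside them on the same strand, a choice made after seeing the data. Further genes were named after their values had been seen: ACTA2, TPM1, CALD1, FLNA, MYH9, VIM, FN1, ZEB1, SNAI1, MMP14, COL1A2, COL3A1, CDH1, KRT8, KRT18, SMAD7, THBS1, ID1, ID2, ID3, NQO1, TXNRD1, ATF4, DDIT4, XBP1, the genes of 4 symbol families and the genes that hold a small RNA. The values of a few genes that the rule or the lists would name are not reported here.

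The alternatives set then were pseudocounts of 0.1 and 1 RPKM, 4 rescalings of the MYOCD library (same total RPKM, median log2 ratio of 0, steady reference genes at 0, and a mean of log2 ratios trimmed by 30% of ratios and 5% of abundances at each end), 3 other filters (none, RPKM of at least 5, mean RPKM of at least 1), thresholds of 1.5-fold and 4-fold, every row counted, the 10 most abundant genes left out, and random lists not matched on expression. Alternatives added after seeing the data were the counts without gene models under 200 nt, the counts over the protein-coding genes defined above, and those genes as the background of the lists. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedure was tested on simulated data for the MYOCD against WT comparison with 16508 genes, 200 of them changed and an assumed noise SD of 0.3 on the log2 scale. It called 41% of the genes changed 2-fold, 100% of those changed 4-fold and 0.0552% of unchanged genes. The simulated noise was equal at every expression level, held no read-counting noise and left genes at 0 in WT at 0. These rates follow from the assumed SD and are no error rates for the 2 real libraries. Of 200 lists with no change, 6% stood apart, and a list of 25 changed genes reached percentile 100.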

Results

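RNA of A549 lung adenocarcinoma cells was profiled in 2 libraries, 1 of wild-type cells (WT) and 1 of cells overexpressing MYOCD, to compare their transcriptomes. There were no replicates, so each value below is that of a single library. The deposited RPKM summed to 886700 in WT and 880876 in MYOCD. An RPKM of at least 1 was reached by 16161 genes in WT and 15973 in MYOCD, with medians of 10.6 and 10.5 RPKM among them. Genes encoded by the mitochondrial genome held 26.5% and 25.8% of the RPKM. The genes with the highest means were MT-ATP8, with 81864 RPKM in WT and 87505 in MYOCD, MT-ND4L, MT-RNR2, MIR663AHG and MT-CO2. MT-ATP8 and MT-ND4L are short models of 207 and 297 nt. Their exons overlap those of MT-ATP6 and MT-ND4 on the same strand, so their values are uncertain where reads were shared. The depth of the libraries is unknown.

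MYOCD itself, on chromosome 17 from 12665890 to 12768949 on the plus strand (GRCh38), stood at 0.304 RPKM in WT and 48.6 RPKM in MYOCD. This was a log2 change of 5.93 with the pseudocount and a ratio of 160.2 between the deposited values, in the direction of the labels. Among protein-coding genes with no small RNA or short transcript and at least 5 RPKM in the higher library, the largest gains after MYOCD included NPNT (0.910 and 15.03 RPKM in WT and MYOCD), which encodes the matrix protein nephronectin, RNF128 (0.199 and 6.82), an E3 ubiquitin ligase, and IGFN1 (0.146 and 5.45). PORCN, the acyltransferase that lipidates Wnt proteins, stood at 6.53 RPKM in WT and 57.6 in MYOCD. The neural cadherin gene CDH2 stood at 2.76 and 24.3 RPKM, the collagen gene COL5A1 at 4.27 and 34.0, and SPOCK1, which encodes the proteoglycan testican, at 0.848 and 9.18. POU6F1 (log2 change of 2.96), CREG2 (2.89), CCBE1 (2.89) and GLIPR1 (2.89) completed the 12 largest of this set.

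At the other end of the same set, ANKRD1, which encodes a cardiac ankyrin repeat protein, stood at 10.5 RPKM in WT and 0.496 in MYOCD, a log2 change of -3.47. INHBB, the gene of the beta B subunit of activin and inhibin, had 39.7 RPKM in WT and 5.13 in MYOCD. The fatty acid hydroxylase genes CYP4F11 (35.9 and 4.89 RPKM) and CYP4F3 (25.2 and 5.05) were lower in MYOCD, as was CYP1B1 (92.3 and 19.6), a cytochrome that oxidises steroids and aromatic hydrocarbons. The fibrinogen alpha chain gene FGA (20.8 and 4.03 RPKM), the keratin gene KRT4 (5.42 and 0.785), ZNF585A (6.23 and 0.987) and TFPI (76.1 and 17.6), which encodes an inhibitor of the coagulation pathway started by tissue factor, were also among the 12 smallest of this set. The remaining 3, RPL36A-HNRNPH2, AC006486.9 and RP11-1012A1.4, share exons with other genes on the same strand, as do ZNF585A (with AC012309.1) and CYP1B1 (with RMDN2-AS1). CYP4F genes are close paralogs, and how reads common to them were assigned is not given in the sources used here.

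**Figure D1:**
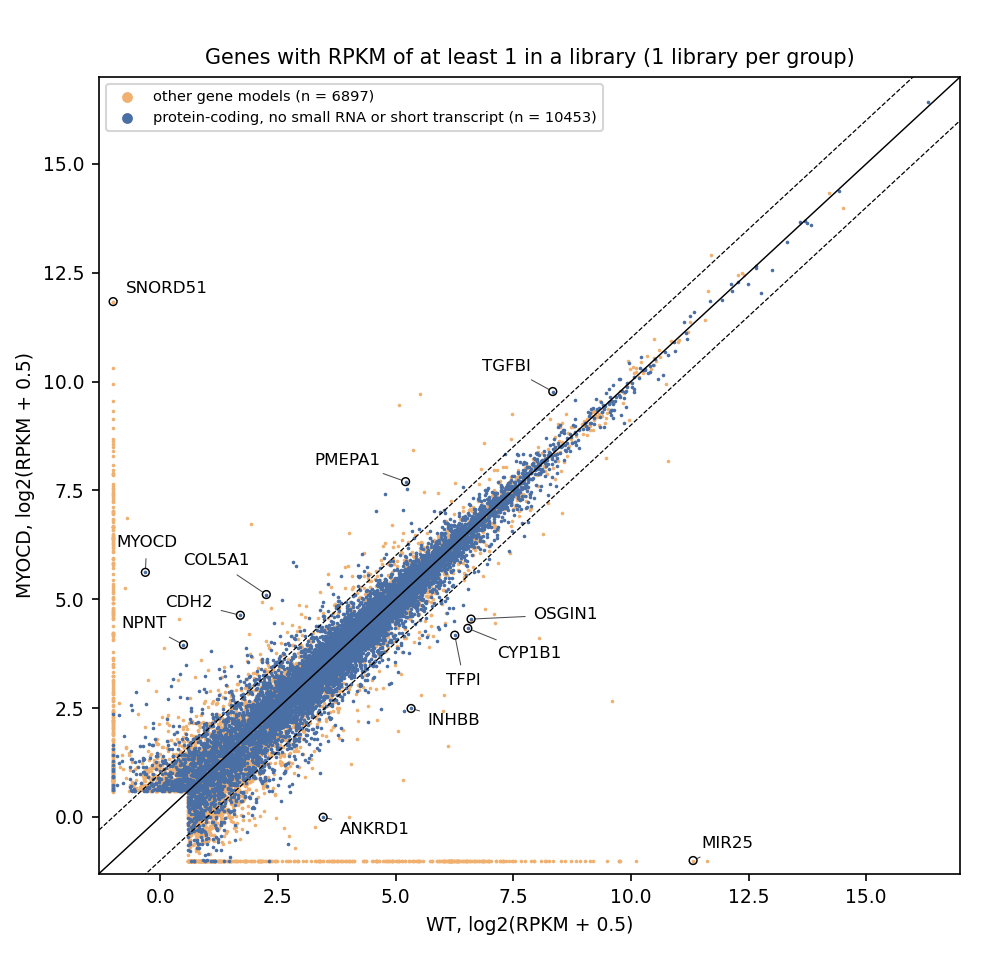
Expression in the WT library (x axis) against the MYOCD library (y axis), both as log2(RPKM + 0.5), for 17350 genes with an RPKM of at least 1 in a library. Each point is a gene, dashed lines mark 2-fold, blue points are the 10453 protein-coding genes with no small RNA or short transcript and orange points are other gene models; MYOCD, COL5A1 and CDH2 lie above the band, ANKRD1 and INHBB below it, and models listed at 0 in 1 library line the axes.

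Over the 17350 genes counted, 940 were higher and 1102 were lower in MYOCD by 2-fold or more, and the median log2 change was -0.00. Among the 10453 protein-coding genes with no small RNA or short transcript the numbers were 295 and 320, or 5.88% of genes against 11.8% over all. With no second library in either group, these numbers have no replicate check.

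Mesenchymal genes stood higher in MYOCD as a group. Of 21 list members past the filter 7 were higher and 0 were lower by 2-fold or more, and their median log2 change of 0.44 lay at percentile 99.98 of random lists. With an RPKM of at least 5 in a library, 3 of 12 members were higher and the median was 0.29, at percentile 99.6. The 7 higher among all 21 were CDH2, COL5A1, COL1A1 (3.05 and 14.3 RPKM in WT and MYOCD), SNAI2, ITGB3, FOXC2 and MMP14. SNAI2 (0.224 and 1.72 RPKM) encodes a transcriptional repressor of epithelial genes and MMP14 (1.18 and 3.06) a matrix metalloproteinase. ITGB3 stood at 0.540 and 2.14 RPKM and FOXC2 at 0.153 and 1.03. Vimentin (VIM) stood at 350.3 and 493 RPKM, ZEB1 at 6.85 and 9.47, SNAI1 at 2.24 and 3.75 and fibronectin (FN1) at 71.0 and 71.2, all under 2-fold. The fibroblast markers share 6 genes with this list, COL1A1, COL1A2, COL3A1, FAP, PDGFRB and THY1. Of these markers 3 passed the filter and COL1A1 alone was at or beyond 2-fold, while COL1A2 stood at 0 and 0.174 RPKM, COL3A1 at 0.109 and 0.138, FBLN1 at 34.3 and 27.6, and THY1 at 1.91 and 0.959.

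Genes of the TGF-beta pathway did not stand apart as one group, but 5 of its 30 members were higher by 2-fold or more and 0 were lower. They were PMEPA1 (36.6 and 207.8 RPKM), which encodes a membrane protein that restrains TGF-beta signalling, the integrin gene ITGB6 (2.34 and 10.6), the collagen IV genes COL4A1 (13.8 and 45.6) and COL4A2 (30.7 and 78.7), and TGFBI (324 and 874), a matrix protein gene induced by TGF-beta. SMAD7 stood at 10.8 and 11.8 RPKM and THBS1 at 32.4 and 16.4. The list median of -0.03 lay at percentile 31.1. It was 0.05 (percentile 30.8) when the steady reference genes were set to 0, -0.09 (8.57) with an RPKM of at least 5 and -0.09 (9.68) without a filter.

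Smooth muscle contractile genes, a class of MYOCD and SRF targets, had 2 members higher and 1 lower among 22 past the filter. TAGLN, which encodes transgelin, stood at 2.34 RPKM in WT and 6.93 in MYOCD, and the LIM protein gene PDLIM7 at 20.5 and 52.7. The myosin light chain kinase gene MYLK stood at 37.8 and 17.98 RPKM. Smooth muscle actin (ACTA2) stood at 8.28 and 8.97, tropomyosin (TPM1) at 192 and 320.4 and caldesmon (CALD1) at 85.9 and 138. Members under 1 RPKM in both libraries, which did not pass the filter, included CNN1 (0.355 and 0.328), ACTG2 (0 and 0.166), LMOD1 (0.0752 and 0.139), MYL9 and DES. The list median of 0.18 lay at percentile 97.3, within the central range of random lists. It lay outside that range with a pseudocount of 0.1 RPKM (98.2) and with filters of at least 5 RPKM (100) or a mean of 1 (98.5). The same held with trimmed scaling (97.6) and against protein-coding genes alone (98.03). Without a filter, 31 members had a median of 0.11 at percentile 94.2, further inside the central range.

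SRF and actin cytoskeleton target genes stood higher as a group, with 27 of 32 members above 0, a median of 0.30 and a percentile of 100, although 0 were higher by 2-fold. Nonmuscle myosin (MYH9) stood at 137 RPKM in WT and 252 in MYOCD, filamin (FLNA) at 359 and 515 and gamma actin (ACTG1) at 4494 and 4837. The members lower by 2-fold were the immediate early gene FOS (4.67 and 1.02) and CTGF (32.7 and 14.1), which encodes connective tissue growth factor. Of the cardiac and sarcomere genes 9 passed the filter, with NKX2-5, a cardiac homeobox gene, higher (3.19 and 8.77 RPKM) and ANKRD1 and the troponin C gene TNNC1 (3.07 and 0.284) lower. Their median of -0.06 lay at percentile 37.2 and changed sign when the steady reference genes were set to 0. In the list of skeletal muscle transcription factor and miRNA host genes, dystrophin (DMD) was the 1 member of 10 at or beyond 2-fold, with 0.101 and 2.48 RPKM. Its most abundant others were MKL1 (25.3 and 34.3), a relative of MYOCD, and KLF5 (30.1 and 23.0), and the list lay at percentile 74.7 with a median of 0.08, or 31.6 with a median of -0.08 over 12 members without a filter.

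Epithelial genes went both ways. Higher in MYOCD by 2-fold or more were MUC1 (2.39 and 6.95 RPKM), EPCAM (0.889 and 2.57) and the claudin gene CLDN2 (3.18 and 7.48), and lower were plakoglobin (JUP, 74.8 and 22.0), the epithelial transcription factor gene ELF3 (123 and 56.0) and LLGL2 (23.6 and 10.6). The remaining 21 of 27 members lay under 2-fold, among them E-cadherin (CDH1, 35.01 and 35.8 RPKM) and the keratin genes KRT8 (1523 and 1059) and KRT18 (1647 and 1134). The list median was 0.03, at percentile 61.5. Of the alveolar and airway lineage genes, 10 passed the filter: HNF4A was higher (4.36 and 10.7 RPKM), the mucin gene MUC5B was lower (3.01 and 0.978), CAV1 stood at 232 and 318, and the median of 0.20 lay at percentile 88.1.

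**Figure D2:**
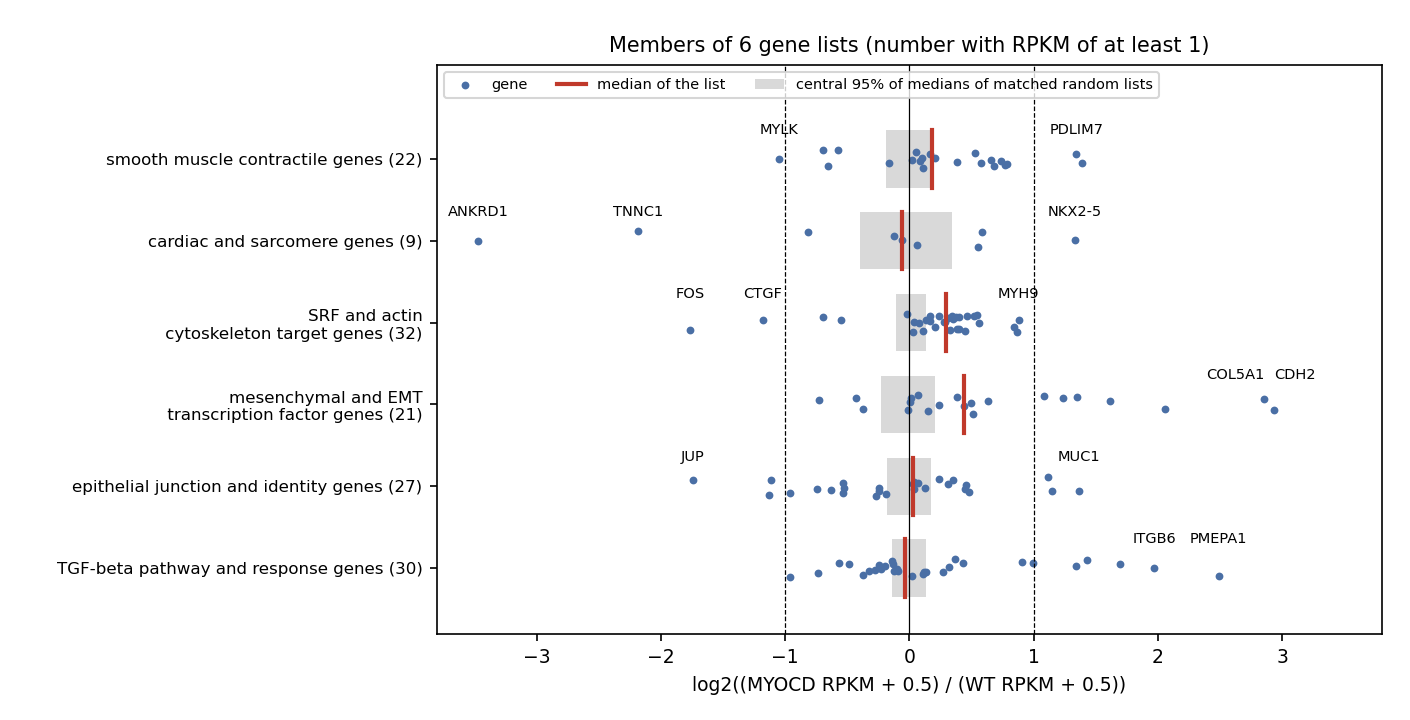
Log2 change between the MYOCD and WT libraries (x axis, pseudocount 0.5 RPKM) of the members of the 6 primary gene lists with an RPKM of at least 1 in a library. Points are genes, red lines are list medians, grey bars span the central 95% of medians of matched random lists and dashed lines mark 2-fold; the medians of the mesenchymal (0.44) and SRF (0.30) lists lie outside the grey bars.

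NRF2 target genes, which encode enzymes of the antioxidant response, were lower as a group, with 22 of 26 members below 0, a median of -0.32 and a percentile of 0. OSGIN1 (96.8 and 22.8 RPKM) and the sulfiredoxin gene SRXN1 (224 and 109) were lower by 2-fold or more, while the ferritin light chain gene FTL stood at 6924 and 4169, thioredoxin reductase (TXNRD1) at 929 and 531 and NQO1 at 888 and 604. Cholesterol synthesis genes were also lower, with 22 of 24 members below 0, a median of -0.36 and a percentile of 0.03. The 3 members lower by 2-fold or more included HMGCS1 (70.2 and 27.5 RPKM), the gene of the synthase that forms HMG-CoA.

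BMP and ID genes had a median of -0.54 over 16 members, at percentile 0.02. BMP4 (14.01 and 5.90 RPKM), ATOH8 (7.09 and 3.22) and the BMP antagonist gene GREM1 (1.05 and 0.148) were lower by 2-fold or more, and the BMP-responsive genes ID1 (225 and 150.2), ID2 (206 and 107) and ID3 (267 and 182) lay under 2-fold. Interferon-stimulated genes had a median of -0.39 over 17 members, at percentile 1.48, with ISG20 (6.85 and 2.48 RPKM) lower by 2-fold and OAS3 at 14.2 and 19.5. The place of the interferon list was lost with a filter on the mean RPKM (median -0.05, percentile 39.3) and without a filter (-0.08, 26.9), and with at least 5 RPKM the median was again -0.39 over 7 members, at percentile 3.17. The place of the BMP list was lost without a filter (5.63). Inflammatory and NF-kB genes lay at percentile 3.54 with a median of -0.20 over 21 members. In that list the cytokine gene IL11 (5.48 and 31.3 RPKM) and the chemokine gene CXCL5 (64.4 and 132) were higher, and the cyclooxygenase gene PTGS2 (17.8 and 6.99) and ICAM1 (1.24 and 0.152) were lower by 2-fold or more.

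Genes of the unfolded protein and integrated stress responses were higher as a group, with 21 of 23 members above 0, a median of 0.32 and a percentile of 99.99. ATF4 stood at 112 RPKM in WT and 151 in MYOCD, XBP1 at 26.7 and 40.4, DDIT4 at 65.7 and 108 and the endoplasmic reticulum chaperone gene HSP90B1 at 336 and 422. ATF3 went the other way (6.13 and 2.14 RPKM) and was the 1 member at or beyond 2-fold, while the amino acid transporter gene SLC7A5 stood at 576 and 591. Heat shock genes had 13 of 15 members above 0, a median of 0.19 and a percentile of 98.1, with HSP90AA1 at 857 and 1069 RPKM, HSPA8 at 1067 and 1178 and HSPD1 at 548 and 635. Against random lists not matched on expression this percentile was 94.3.

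**Figure D3:**
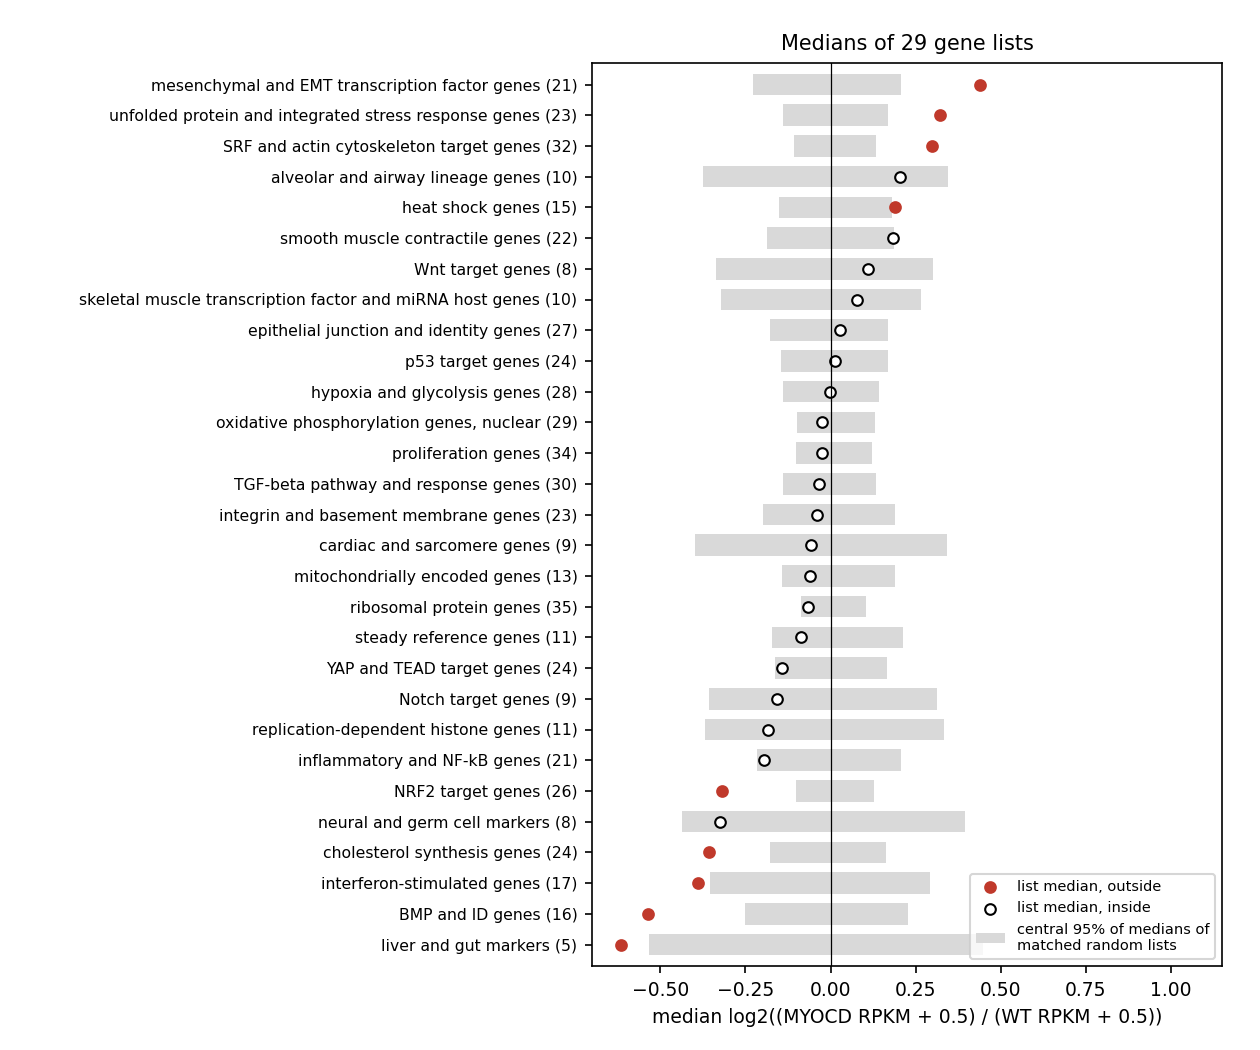
Median log2 change (x axis, pseudocount 0.5 RPKM) of 29 gene lists, with the number of members past the filter in brackets. Grey bars span the central 95% of medians of matched random lists; red points, from the mesenchymal list (0.44) to the liver and gut markers (-0.62), lie outside them, and the near-0 medians of 9 lists changed sign or became 0 under another scaling.

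YAP and TEAD target genes had 1 member higher and 4 lower by 2-fold or more among 24, a median of -0.14 and a percentile of 4.36. NT5E stood at 4.01 and 11.4 RPKM, and beside ANKRD1 and CTGF the lower members were the kinase gene LATS2 (12.6 and 5.75) and RBMS3 (1.73 and 0.587). Among 9 Notch genes the receptor gene NOTCH3 was lower (17.5 and 6.54), the ligand genes JAG1 (23.7 and 46.2) and JAG2 (20.8 and 16.98) lay under 2-fold, and the median of -0.16 lay at percentile 18.1. Of 8 Wnt target genes, the Wnt inhibitor gene DKK1 (212 and 87.7 RPKM) and BMP4 were lower, CCND1 stood at 166 and 133, and the median of 0.11 lay at percentile 77.6 but was -0.07 with an RPKM of at least 5 (percentile 28.6) and -0.04 without a filter (43.8). Integrin and basement membrane genes, at percentile 33.6 over 23 members, had 2 members higher and 1 lower by 2-fold or more, among them the laminin gene LAMA4 (0.145 and 1.13 RPKM) and the collagen gene COL4A3 (1.47 and 0.202). In the hypoxia and glycolysis list, at percentile 47.2 over 28 members, CA9 (0.201 and 1.47) and PFKFB4 (3.23 and 7.11) were higher, and ADM (68.0 and 25.2) and NDRG1 (66.2 and 30.5) were lower.

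Proliferation genes lay close to their WT values, with 0 of 34 members at or beyond 2-fold and a percentile of 25.7. TOP2A stood at 192 RPKM in WT and 194 in MYOCD, CCNB1 at 186 and 191, and PCNA at 257 and 230.4. Of 24 p53 target genes GDF15 (62.7 and 29.1) alone was at or beyond 2-fold, MDM2 stood at 232 and 169 and BAX at 229 and 262, and the median of 0.01 lay at percentile 51.8. Nuclear oxidative phosphorylation genes had 0 of 29 members at or beyond 2-fold, a percentile of 23.1 and values such as COX7C at 665 and 590.01, ATP5B at 516 and 545, and ATP5G1 at 291 and 268. The medians of the integrin, hypoxia, proliferation and oxidative phosphorylation lists lay between -0.04 and -0.00 and changed sign when the steady reference genes were set to 0, that of the hypoxia list also with both libraries at the same total RPKM and without a filter.

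Markers of other cell types were few. Endothelial markers had 2 members past the filter, ESAM (1.40 and 3.497 RPKM) and EGFL7 (23.7 and 18.2), and blood cell markers had 2, CD68 (18.3 and 25.1) and CD14 (2.31 and 1.17). Without a filter, 9 blood cell markers had a median of 0.34 at percentile 98.3, of which 7 were under 1 RPKM in both libraries, 6 endothelial markers lay at percentile 22.1 and 9 fibroblast markers at 74.5. The neural and germ cell list lay at percentile 6.12 with a median of -0.32 over 8 members, with RBFOX3 (14.2 and 3.49) and MAP2 (2.78 and 0.978) lower and TUBB3 at 76.4 and 96.4. Liver and gut markers lay at percentile 1.51 with a median of -0.62 over 5 members, with FGA lower by 2-fold and the other fibrinogen genes FGB at 12.6 and 8.003 and FGG at 13.8 and 10.2, but at percentiles of 2.59 to 7.79 with a pseudocount of 1 RPKM, with the steady reference genes at 0 or without a filter. Ribosomal protein genes (percentile 6.80, 35 members, RPS19 at 2379.8 and 2259, RPS16 at 2346 and 2005, RPL4 at 2042 and 1911) and mitochondrially encoded genes (percentile 19.7, 13 members) each had a median of -0.06 that changed sign when the steady reference genes were set to 0. Histone genes had a median of -0.18 over 11 members at percentile 15.5, with HIST1H2BK at 22.7 and 19.4, HIST1H1C at 16.2 and 11.4 and HIST1H2BD at 12.8 and 10.3. The 11 steady reference genes had a median of -0.09 at percentile 13.8, with GPI at 449 and 456, VCP at 248 and 235 and PSMB4 at 156 and 159, and 0 members of these 4 lists were at or beyond 2-fold. In all, 29 lists had a percentile, of which 5 lay at or under 2.5 and 4 at or above 97.5, where 1.45 were due by chance for lists of unrelated genes.

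Across all gene types, the 24 most extreme log2 changes belonged to gene models under 200 nt, chiefly microRNA and small nucleolar RNA genes. Each was listed at 0 in 1 library, 12 in WT and 12 in MYOCD. SNORD51, on chromosome 2 from 206161878 to 206161957, was listed at 0 in WT and 3658 RPKM in MYOCD, and MIR93, on chromosome 7 from 100093768 to 100093847, at 0 and 3653. MIR2116 was listed at 3152 in WT and 0 in MYOCD. MIR25, on chromosome 7 from 100093560 to 100093643 and so within the same cluster as MIR93, was listed at 2561 in WT and 0 in MYOCD. The other models higher in MYOCD were MIR4484, MIR8078, SNORD55, SNORD127, Six3os1_1, SCARNA18, VTRNA1-3, PVT1_3, SNORD12C and SNORD116-2, and those lower were MIR4688, MIR6719, MIR3682, MIR7161, SNORD11, MIR6723, MIR1282, MIR4516, DLEU2_2 and SNORD14A. Among genes with at least 5 RPKM in the higher library, 76.9% of the 542 models under 200 nt were at or beyond 2-fold, against 4.38% of the 10186 models of 1000 nt or more. The naming rule, with its later repeat among protein-coding genes, named 148 genes. Of these, 64 have exons that overlap another gene on either strand, such as TAGLN with PCSK7, GLIPR1 with KRR1 and CYP1B1 with RMDN2. Their values are uncertain where reads were shared.

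**Figure D4:**
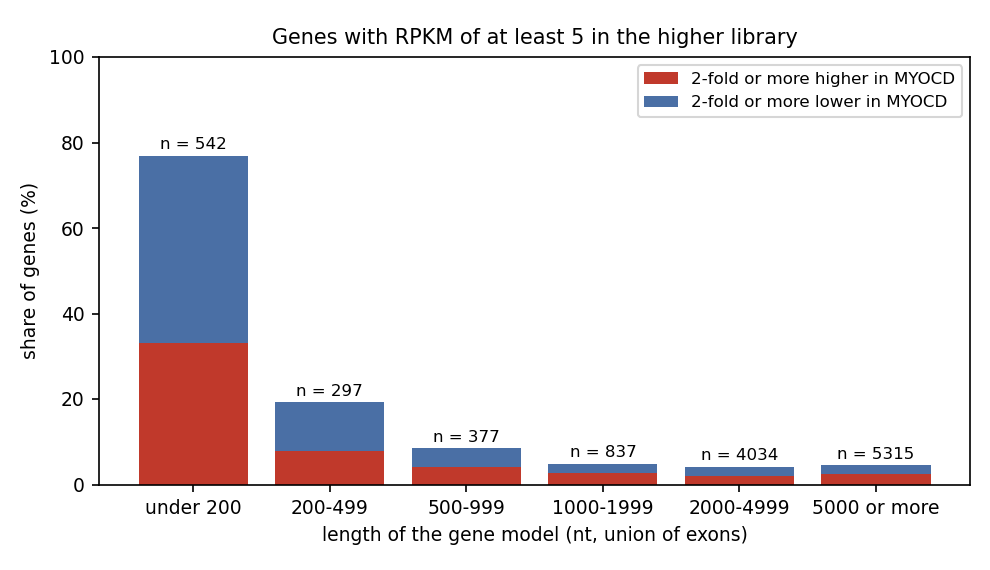
Share of genes (y axis, percent) that were higher or lower in MYOCD by 2-fold or more, by length of the gene model (x axis, nt), among genes with an RPKM of at least 5 in the higher library. Bars are stacked from 0 and n is the number of genes; the share is 76.9% for models under 200 nt and 4.14% for models of 2000 nt to under 5000 nt.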

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

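The counts of 940 higher and 1102 lower genes moved by over 1.5 times in 4 settings. They were 450 and 510 with an RPKM of at least 5 in a library, 2007 and 2296 at 1.5-fold, 327 and 369 at 4-fold, and, chosen after seeing the data, 295 and 320 over protein-coding genes with no small RNA or short transcript. The threshold makes the moves at 1.5-fold and 4-fold. In the others the share of genes at or beyond 2-fold was also lower, at 8.39% and 5.88% against 11.8%, so the genes left out were more often at or beyond 2-fold. Without gene models under 200 nt, also chosen after seeing the data, the counts were 737 and 840, or 9.42% of genes. Pseudocounts of 0.1 and 1 RPKM gave 1208 and 1432, and 741 and 839. Setting the steady reference genes to 0 gave 1074 higher and 1019 lower, which put the higher share at 51.3% in place of 46.0%. The smooth muscle list passed the upper limit of 97.5 in 5 settings: pseudocount 0.1 RPKM (median 0.21, percentile 98.2), trimmed scaling (0.18, 97.6), RPKM of at least 5 (0.53, 100), mean RPKM of at least 1 (0.20, 98.5) and, chosen after seeing the data, protein-coding genes as background (0.18, 98.03). The cause was not tested, and the list's main percentile of 97.3 lay close to the limit. Trimmed scaling moved log2 changes by only -0.00311. Median scaling moved them by a like -0.00401 and left the percentile at 97.47, so passing the limit there shows no effect of scaling. Without a filter the smooth muscle list lay at 94.2. The other 5 primary lists and MYOCD kept their side of the limits under every alternative run, but the mesenchymal list had 3 of 12 members higher by 2-fold and a median of 0.29 (percentile 99.6) with an RPKM of at least 5, and 5 higher with a pseudocount of 1 RPKM or a mean RPKM of at least 1. Among the other lists, interferon-stimulated genes lost their place under 3 filters, liver and gut markers under 3 settings (pseudocount 1, steady genes at 0, no filter), BMP and ID genes without a filter (median -0.19) and heat shock genes without matching, while inflammatory (percentile 2.19, no filter), YAP (1.59, RPKM of at least 5) and lineage genes (97.52, RPKM of at least 5) gained one, and blood cell markers, with too few members past the filter for a percentile, lay at 98.3 without a filter. Of the genes named by rule, 11 fell under 2-fold with a pseudocount of 1 RPKM (among them ATOH8, EPCAM, ESAM, FOXC2, GREM1, ICAM1, LAMA4, MAP2, PFKFB4, RBMS3), 5 with steady genes at 0 (ATOH8, LATS2, MYLK, RBMS3, SRXN1), and JAG1 passed 2-fold with the latter. Of the genes named after their values were seen, COL21A1, COL22A1, HOXA2 and MMP14 fell under 2-fold with a pseudocount of 1 RPKM and HOXA3 passed it with steady genes at 0. No list that stood apart changed the sign of its median. Genes at or beyond 2-fold, MYOCD among them, could not have reversed. A pseudocount keeps the sign of a change, and the rescalings shifted log2 changes by at most 0.0871. The planned counting interval was not run because whole reads were not recovered, so the depth behind low values is unknown. No paired analysis was possible because each group has 1 library.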

Other observations

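The comparisons and tests of this part were chosen after the patterns were seen, except the tests of direction among short models and of single cultures, which were chosen before their results were seen. Symbol families with at least 8 protein-coding members were compared in the same way as the gene lists. Of 159 families, 5 lay at or under percentile 2.5 and 7 at or above 97.5, where 7.95 were due by chance. The 9 HOXA genes, which encode homeobox factors of positional identity, had a median log2 change of 0.92 at percentile 100. Their medians were 0.91 to 0.99 over the rescalings. A rescaling moves nearly all log2 changes by the same amount, so such ranges, here and for the families below, are no separate support. HOXA5 stood at 2.05 RPKM in WT and 9.68 in MYOCD, HOXA2 at 1.26 and 3.21 and HOXA3 at 10.2 and 19.8, while HOXA10 stood at 4.13 and 3.09. The 15 COL genes had a median of 0.45 at percentile 99.9 and medians of 0.44 to 0.53 over the rescalings. The set includes COL4A3BP, which encodes no collagen and whose own log2 change is the median, and leaves out COL4A2. By 2-fold or more, 6 of the COL genes were higher and 3 were lower. Beyond those of the gene lists, COL6A1 (5.08 and 11.3 RPKM), COL6A2 (5.69 and 12.9) and COL22A1 (0.185 and 1.22) were higher by 2-fold or more, and COL26A1 (2.82 and 0.797) and COL21A1 (1.26 and 0.303) were lower.

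The 18 cytochrome P450 genes had a median of -0.52 at percentile 0.01, between -0.53 and -0.45 over the rescalings, and 7 of them were lower by 2-fold or more with 0 higher. Beside CYP4F11, CYP4F3 and CYP1B1, CYP4F12 stood at 3.43 RPKM in WT and 0.671 in MYOCD and CYP27B1, which activates vitamin D, at 3.90 and 1.27. CYP24A1, which degrades it, stood at 826 and 801. The 356 ZNF genes, most of them encoding zinc finger factors of low abundance, had a median of -0.17 at percentile 0, between -0.17 and -0.09 over the rescalings, with 22 lower and 5 higher by 2-fold or more.

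The concentration of extreme changes in very short gene models is a candidate artefact of the unit. The share at or beyond 2-fold was 17.6 times as high for models under 200 nt as for models of 1000 nt or more. That ratio describes the pattern and does not tell this explanation from changes of small RNAs in the cells. Among models with 1 transcript, the median WT value above 0 was 854 RPKM at 80 to 89 nt, 75.4 at 100 to 119 nt and 6.11 at 150 to 199 nt, a steeper course than division by full length gives. In WT, SNORD11 and MIR7161, both of 84 nt, had equal values of 854 RPKM, and MIR25, also of 84 nt, had 3 times as much, so such values may rest on few fragments divided by a small effective length. AL355480.2, of the same length, had 326 RPKM and did not follow this step. Of the changed short models, 180 were higher and 237 were lower in MYOCD, so 56.8% went the majority way. A shift of nearly all of them in 1 direction was thus not seen. A weaker common shift cannot be excluded, because values that rest on few fragments would go both ways in any case. Changes of single small RNAs in the cells stay open.

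Several protein-coding genes that hold a small RNA or a transcript under 200 nt had changes of over 4-fold, among them RUBCN (781 RPKM in WT and 5.81 in MYOCD), DGCR8 (263 and 16.8), PKD1 (45.5 and 833) and SCRIB (33.1 and 706). Reads of the small feature counted into the gene are a candidate explanation. Of 57 protein-coding genes at or beyond 4-fold with at least 5 RPKM in the higher library, 15 (26.3%, exact 95% binomial interval 15.5% to 39.7%) held such a feature, against 16.1% of 9300 genes under 2-fold, a ratio of 1.63. The interval includes the lower share, so the genes are too few to decide. A change of these genes in the cells was not tested separately.

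The 12 mesenchymal and TGF-beta genes at or beyond 2-fold, CDH2, COL1A1, COL4A1, COL4A2, COL5A1, FOXC2, ITGB3, ITGB6, MMP14, PMEPA1, SNAI2 and TGFBI, might follow from MYOCD overexpression, a hypothesis these data cannot decide. Fibroblasts in the culture are argued against, since COL1A2, COL3A1, DCN and LUM together gained 0.254 RPKM where COL1A1 gained 11.2, a ratio of 0.0226. Scaling shifted log2 changes by at most 0.0871, and the running median over 500 protein-coding genes of like length lay at most 0.0594 from 0, against a lowest change of 1.08 in the set, so neither accounts for it. These genes were picked for their size of change, and the whole TGF-beta list had a median of -0.03. With 1 library per group, an effect of MYOCD cannot be told apart from a difference between 2 single cultures.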
